A study of Mus musculus with 6 samples.

How the data were processed

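RNA from 6 samples of the mouse mammary tumour line 4T1 was measured by RNA sequencing, 3 treated with roscovitine and 3 with the DMSO vehicle, each for 24 h per the labels. Groups and replicate numbers were taken from the sample titles. Each library has its own table of 54848 genes, 54532 with Ensembl identifiers and 316 for loci that the annotation lacks, with the gene's symbol, coordinates, strand, biotype and length. There were 0 value columns of unlabelled samples.

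Per the submitters' processing notes, the tools were HISAT2 2.0.5, a spliced-read aligner, and featureCounts 1.5.0-p3, a program that assigns reads to genes, and the genome build was mm10. The notes give these names with no role or order. The annotation release, the use of strand, and the treatment of reads that map to several places are not given in the sources used here. Overlapping genes, antisense partners and near-identical copies can therefore share reads in ways that the tables do not show. The coordinates in the tables were identical to those of GENCODE M21 (GRCm38, the assembly called mm10) for 53499 of the 54409 identifiers found there, or 98.3%.

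The deposited values are FPKM, fragments scaled to gene length and library size. No label or header names the unit. It was inferred from the values, which are not whole and which, multiplied by gene length, are whole multiples of 1 step per library. Within a tolerance of 0.05 of a multiple, 100% of the values above 0 were whole. The step gives the implied reads per gene, which summed to between 18077614 and 23102345 per library. At a gene length of 1 kb, 1 read was worth between 0.0442 and 0.0569 FPKM, so values near those levels rest on single reads. The library size implied by the deposited FPKM was 0.975 ± 0.005 times the implied reads in vehicle and 1.04 ± 0.01 times in roscovitine (SD, n = 3), so the authors' values carry a further scaling. Median-of-ratios factors recomputed from the deposited values were 1 in every library to 6 digits or better, so this scaling is already in them.

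Read counts are not among the values used, so the planned quasi-likelihood test of counts gave way to the fallback fixed for a normalized unit. Each value was taken as log2(FPKM + 1), and genes with at least 0.5 FPKM in at least 3 libraries were kept, which left 14050. The groups were compared with limma 3.58.1 in R 4.3.3, with a linear model of group alone, moderated variances with an intensity trend, and Benjamini-Hochberg adjustment over all genes tested. A gene counted as changed at an adjusted p under 0.05. Changes are on the log2(FPKM + 1) scale, which understates the change of genes of low level. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

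A set of 37 gene lists was fixed before the data were examined. Of these, 30 were tested with limma's camera, which asks whether a list stands apart from the other genes, at a preset correlation between genes of 0.01, with adjustment over the 30 lists. Camera was repeated with the correlation estimated from the data. That run also tests against the residual degrees of freedom of the 6 libraries rather than the number of genes, so it has less power. Beside it fry was run, which asks whether a list's own genes move one way on balance. Where a symbol had several identifiers, the one with the highest mean FPKM was used. The list of study genes, the housekeeping list and 5 lists of markers of other cell types were described by their values only. The text names all study genes, and the 10 largest rises and 10 largest falls among changed genes. These had a CPM of at least 10 from the implied reads in the higher group, no overlap between the groups, and a symbol that is not a predicted locus, a Rik clone or a pseudogene. From each list it names the up to 3 changed members with the largest change and a CPM of at least 1, and for each other cell type the most abundant member. Other genes are named only as neighbours of these, as the most abundant gene of a library, or among ribosomal RNA and adjacent genes singled out after their values were seen.

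Replicates were compared on the implied reads. The chi-square per gene between libraries of 1 group was 1.91 to 2.87, above the value of 1 that sampling alone gives, so no library was a copy of another. The test was tried on simulated reads for 13781 genes drawn at the real vehicle means and the real depths. In these, 200 genes were changed and a list of 25 more was shifted by a log2 change of -0.4. All genes had 1 dispersion of 0.001, the lowest value allowed. The test recovered 80.6% of the genes changed 1.5-fold, 80.6% of those changed 2-fold and 97.0% of those changed 4-fold. Of its calls, 5.13% were false. In the real data 67.7% of genes changed, so these rates need not hold there. Of 30 unchanged simulated lists, 0 were called. Simulated genes varied independently, so this does not test camera on lists whose genes move together. In the real data the estimated correlation reached 0.262, for cytosolic ribosomal proteins.

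Alternatives fixed before the data were examined were total reads as the only scaling, upper-quartile scaling, no filter, a filter of a CPM of at least 1 in 3 libraries, limma's voom on the implied reads, a block for replicate number, and leaving out each library in turn. Pseudocounts of 0.1 and 0.5 were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, permutation and exact tests and plots. Splicing could not be compared, since the tables give 1 value per gene.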

Results

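The study asked how roscovitine, a small-molecule inhibitor of cyclin-dependent kinases used here against CDK5, changes gene expression in 4T1 cells. 4T1 is an established mouse mammary carcinoma line that serves as a model of triple-negative breast cancer. RNA sequencing was done on 3 libraries of cells treated with roscovitine and 3 of cells given DMSO, for 24 h. The labels print the dose as 10 mM, a unit that could not be checked here. Their extraction text speaks of retinas while the source, tissue and growth fields name 4T1 cells. The vehicle libraries held 23102345, 18077614 and 20704175 implied reads and the roscovitine libraries 19512870, 20050942 and 18428599. Between 21445 and 22710 genes had a value above 0 in a library.

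After roscovitine, 23 of 28 genes of the unfolded protein and integrated stress responses, 25 of 28 of hypoxia and glycolysis, 38 of 41 of cytosolic ribosomal proteins, 25 of 27 of mitosis and 21 of 30 of epithelial identity fell. Of lysosome and autophagy genes 19 of 27 rose, of immediate early genes 17 of 26 and of mitochondrially encoded genes 8 of 13. These were among the 13 of 30 lists that passed camera. All 13 lost the call, at adjusted p = 0.174 to 0.447, with an estimated correlation, a run with fewer degrees of freedom. The largest single rise was that of Colec11, from 0.0325 ± 0.0354 to 16.9 ± 1.24 FPKM, and among the largest falls was that of Neat1, a long noncoding RNA of nuclear paraspeckles, from 43.6 ± 0.367 to 7.05 ± 0.270 FPKM (SD, n = 3). With limma, 9510 of the 14050 genes tested changed, or 67.7%, of which 4780 rose and 4730 fell. A log2 change of at least 1 was reached by 213 of the genes that rose and 338 of those that fell. Vehicle and roscovitine libraries separated on the first principal component, which held 78.2% of the variance, against 6.34% on the second. Pearson's r of log2 values, across genes, was 0.992 to 0.994 between libraries of a group and 0.960 to 0.962 between groups. With limma's voom on the implied reads, which has no pseudocount of 1 FPKM, 688 genes rose and 877 fell by a log2 change of at least 1. With libraries scaled to total reads alone, 5654 genes rose and 3951 fell, and the median log2 change of all genes tested was 0.07.

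The study's own genes moved apart from each other. Cd44, which encodes the hyaluronan receptor CD44 (ENSMUSG00000005087, mm10 chromosome 2, 102811141 to 102901665), rose from 82.8 ± 1.67 to 123 ± 1.64 FPKM, a log2 change of 0.57 ± 0.02 (SE; limma, adjusted p = 2.67e-06). Esrp1, an epithelial splicing regulator that acts on transcripts such as Cd44 (chromosome 4, 11331933 to 11386783), fell from 12.4 ± 0.293 to 8.44 ± 0.770 FPKM (log2 change -0.50 ± 0.06; limma, adjusted p = 0.000312). Cd274, which encodes the checkpoint ligand PD-L1 (chromosome 19, 29367455 to 29388095), fell from 0.936 ± 0.0260 to 0.564 ± 0.0665 FPKM (log2 change -0.31 ± 0.07; limma, adjusted p = 0.00654). Cdk5r1, which encodes the CDK5 activator p35 (chromosome 11, 80477023 to 80481184), rose from 0.383 ± 0.0452 to 1.36 ± 0.155 FPKM (log2 change 0.77 ± 0.08; limma, adjusted p = 0.000155). For each of these 4 genes the 3 libraries of one group all lay above those of the other.

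Cdk5 itself (chromosome 5, 24418241 to 24423530) was at 17.3 ± 0.941 FPKM in vehicle and 16.6 ± 1.73 FPKM in roscovitine, a difference within the spread (log2 change -0.06 ± 0.07; limma, adjusted p = 0.485). Esrp2, the paralog of Esrp1, was at 5.27 ± 0.0299 and 5.63 ± 0.267 FPKM (limma, adjusted p = 0.109). Its roscovitine libraries also all lay above those of vehicle, so such separation is not particular to genes that passed. With total-reads scaling Esrp2 passed the test, at a log2 change of 0.16 and an adjusted p of 0.0130 in limma. Pparg, which encodes the nuclear receptor PPARγ, and Cdk5r2, a further CDK5 activator, lay below the level filter. Pparg was at 0.0539 ± 0.0408 and 0.00559 ± 0.00969 FPKM, and Cdk5r2 at 0.0440 ± 0.0384 and 0.0240 ± 0.0114 FPKM, levels at which a difference was not detectable at this depth. Of the 6 study genes tested, 2 rose, 2 fell and 2 did not pass, and the counts adjusted over the list alone were the same. These genes are the study's own subject, so their directions are not independent evidence.

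**Figure D1:**
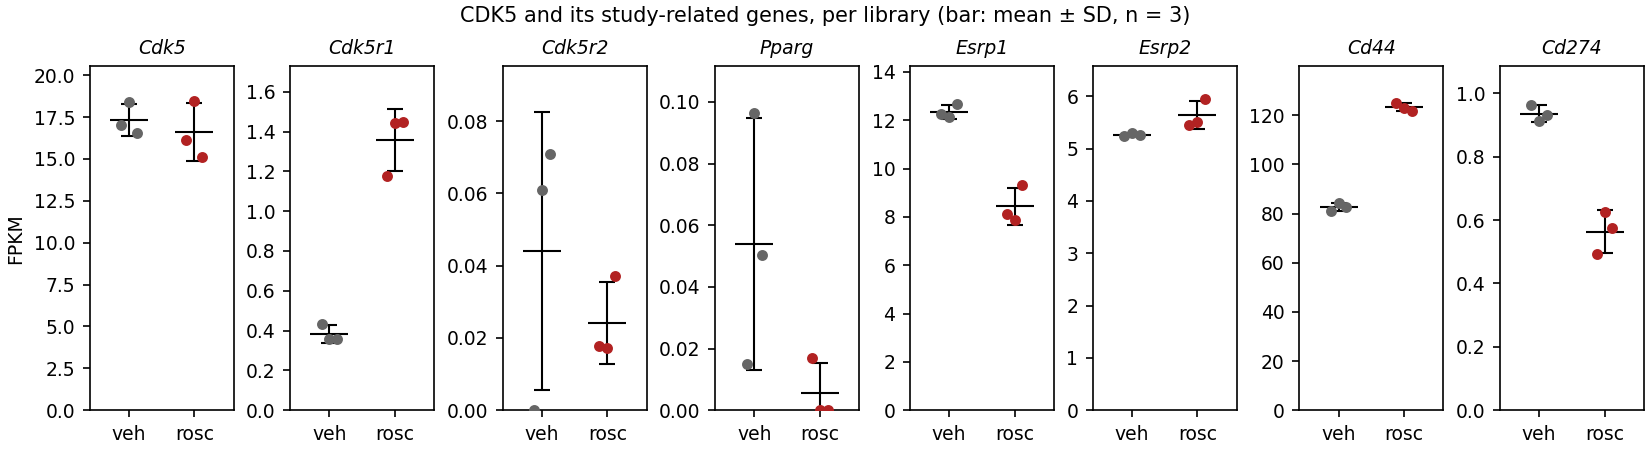
FPKM per library (vertical axis, from 0) of the 8 study genes in vehicle (grey, n = 3) and roscovitine (red, n = 3), where points are libraries and bars give the mean ± SD. Cd44 sits near 82.8 in vehicle and 123 in roscovitine, Esrp1 near 12.4 and 8.44, and the Cdk5 points of both groups overlap.

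The 10 largest rises took in genes of low level in vehicle. Colec11 encodes a secreted collectin and lies on chromosome 12, 28594173 to 28623377. Its rise had a log2 change of 4.12 ± 0.06. Pgam2, the muscle form of phosphoglycerate mutase, rose from 0.575 ± 0.326 to 13.6 ± 0.725 FPKM, and Gsdmc4, a gasdermin gene, from 0.384 ± 0.0726 to 10.5 ± 0.821. Yjefn3 rose from 2.58 ± 0.283 to 28.5 ± 0.777 FPKM and the homeobox gene Dlx3 from 0.143 ± 0.0463 to 5.32 ± 0.349. Apoe, which encodes the lipid carrier apolipoprotein E, rose 6.12-fold to 13.5 ± 0.278 FPKM, and Nr4a2, an orphan nuclear receptor, 5.81-fold to 9.89 ± 0.447. AA986860, the transporter gene Slc16a8 and CT010467.1, annotated as ribosomal RNA, rose 13.8-fold, 8.89-fold and 5.40-fold. In 6 of the 10 the vehicle mean was under 1 FPKM. Of these, Colec11 began 7477 bp beyond the 3' end of the expressed gene Rps7 on the same strand, and Pgam2 and Slc16a8 ended 678 and 1530 bp from the 3' ends of Dbnl and Pick1 on the opposite strand. The others lay farther from expressed genes, Gsdmc4 at 16800 bp, Dlx3 at 43318 bp and AA986860 at 137452 bp. Adjusted p for the 10 genes ran from 1.71e-07 to 4.18e-06 with limma.

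Among the 10 largest falls, Fgfbp1, which encodes a carrier of fibroblast growth factors, fell from 38.0 ± 1.28 to 5.74 ± 0.220 FPKM. H2afx, which encodes the histone variant H2AX, fell from 52.0 ± 1.88 to 8.58 ± 1.33. Adm, the gene of the hypoxia-induced peptide adrenomedullin, fell from 23.8 ± 0.236 to 4.00 ± 0.343 FPKM. Krt19, a keratin of simple epithelia, fell from 88.2 ± 2.44 to 17.0 ± 0.708 FPKM. Chac1 and Trib3, targets of the integrated stress response, fell from 31.3 ± 0.395 to 5.57 ± 0.502 and from 26.9 ± 1.00 to 4.84 ± 0.170 FPKM. The complement gene C3 fell from 20.9 ± 0.444 to 3.50 ± 0.220 and the nucleotide hydrolase gene Dnph1 from 65.3 ± 1.37 to 13.2 ± 0.516 FPKM. Gapdh had the largest log2 change of these 10, -2.75 ± 0.81, but its vehicle libraries read 81.4, 9.05 and 89.8 FPKM against 4.89, 5.81 and 5.21 in roscovitine. Gapdh has many processed pseudogenes, and its value is uncertain. Its limma call (adjusted p = 0.0217) was lost without vehicle replicate 1, vehicle replicate 3 or any 1 roscovitine library and with no level filter, at adjusted p = 0.0510 to 0.0700, and held without vehicle replicate 2 (adjusted p = 6.28e-06).

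**Figure D2:**
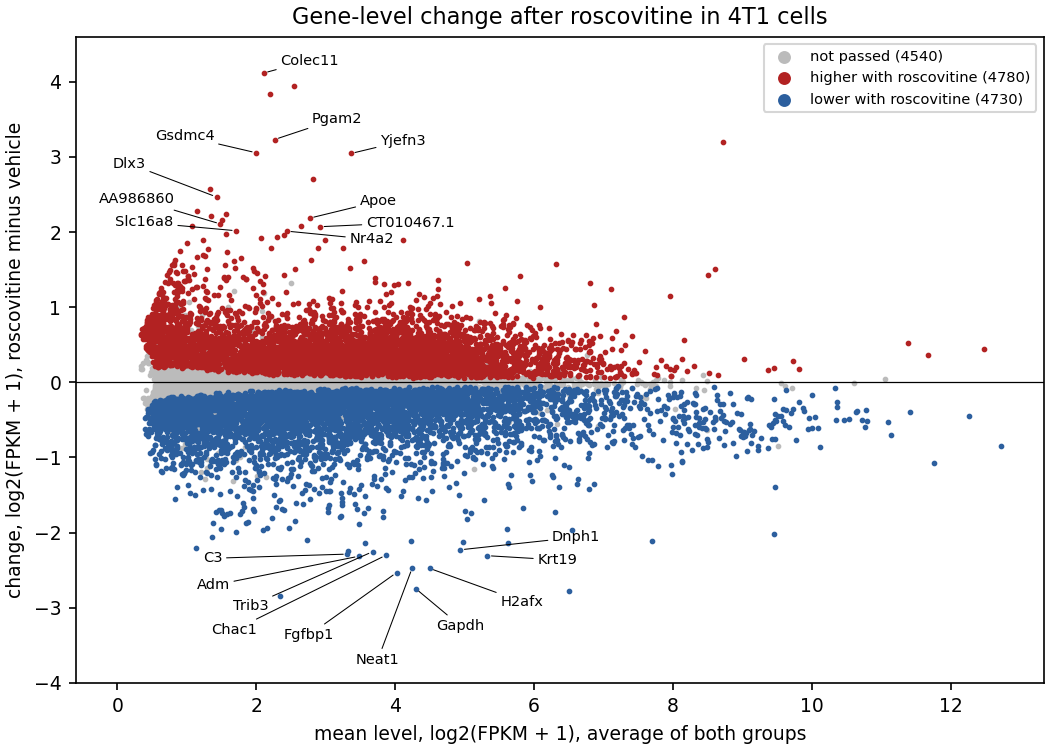
Change in log2(FPKM + 1), roscovitine minus vehicle (vertical axis), against the mean log2(FPKM + 1) of both groups (horizontal axis) for the 14050 genes tested. Red points are the 4780 genes that rose, blue points the 4730 that fell, and grey points did not pass. Labels mark the 10 largest rises and 10 largest falls of the naming rule, from Colec11 at 4.12 to Gapdh at -2.75.

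Mitotic genes fell together. Of 27 tested, 0 rose and 25 fell, with a median log2 change of -0.34 (camera, adjusted p = 2.16e-07), against 2 and 22 with total-reads scaling. The call was lost at an adjusted p = 0.174 with an estimated correlation. Top2a, the topoisomerase of replicating cells, fell from 147 ± 0.791 to 95.3 ± 0.685 FPKM. Cenpf, a kinetochore gene, fell from 19.6 ± 0.788 to 13.0 ± 0.297 and the mitotic kinesin gene Kif23 from 32.3 ± 0.266 to 21.8 ± 0.506.

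Other genes of the cell cycle went both ways. Among 21 genes of CDKs and cyclins, 8 rose and 9 fell (10 and 9 adjusted over the list alone), a balance that turned to 11 and 5 with total-reads and 10 and 7 with upper-quartile scaling. Ccne1 and Ccne2, which encode the E-type cyclins of S-phase entry, rose from 3.0 ± 0.145 to 7.24 ± 0.819 and from 5.50 ± 0.418 to 10.5 ± 0.0979 FPKM. Cdk9, the kinase of transcription elongation, rose from 17.0 ± 0.152 to 31.5 ± 0.561. The list did not stand apart in camera (median log2 change 0.06, adjusted p = 0.638). Of 29 replication and E2F target genes, 9 rose and 14 fell (camera, adjusted p = 0.469). The helicase subunit gene Mcm6 fell from 63.0 ± 1.26 to 35.1 ± 0.318 FPKM and the ligase gene Lig1 from 35.7 ± 0.614 to 25.03 ± 0.713, while the nuclease gene Fen1 rose from 5.84 ± 0.275 to 10.4 ± 0.414. The list's median of -0.08 became 0.00 with total-reads scaling.

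In the histone list, 0 of 12 rose and 4 fell (0 and 3 adjusted over the list alone; median log2 change -0.19; camera, adjusted p = 0.190). The first of them, H1f0, fell from 1410 ± 14.7 to 348 ± 6.59 FPKM. It encodes a linker histone that is also made outside S phase. The list was drawn up for replication-dependent histones and has 27 members, of which 12 passed the level filter. Its values therefore say little about the other histone genes. Hist1h1c fell from 7.39 ± 0.345 to 2.80 ± 0.662 FPKM and Hist1h4d from 1.30 ± 0.219 to 0.567 ± 0.145. Of 24 p53 targets, 6 rose and 13 fell (median -0.15; camera, adjusted p = 0.144). Gadd45a fell from 16.7 ± 0.543 to 5.31 ± 0.410 FPKM, the death receptor gene Fas from 2.86 ± 0.318 to 0.424 ± 0.0621 and Bbc3, which encodes PUMA, from 9.54 ± 0.350 to 3.64 ± 0.218. Of 24 genes of homologous recombination and the Fanconi pathway, 5 rose and 14 fell (median -0.22; camera, adjusted p = 0.0863). Brip1 fell from 5.58 ± 0.461 to 2.93 ± 0.0631 FPKM, Rad51b from 1.86 ± 0.136 to 0.738 ± 0.178 and Fancd2 from 4.86 ± 0.157 to 2.78 ± 0.132.

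Epithelial genes fell, with 21 of 30 lower and 3 higher (median log2 change -0.44; camera, adjusted p = 0.00101), against 20 lower and 7 higher with total-reads scaling. The camera call was lost at an adjusted p = 0.174 with an estimated correlation. Beside Krt19, the simple-epithelium keratin gene Krt18 fell from 671 ± 6.64 to 339 ± 5.75 FPKM and the tight-junction gene Tjp3 from 1.75 ± 0.112 to 0.594 ± 0.110. In the basal and squamous list, 6 of 7 fell and 1 rose (median -0.72; camera, adjusted p = 0.00652, and adjusted p = 0.174 with an estimated correlation). Only these 7 of the list's 19 members passed the level filter, and other basal keratin genes were among those below it. The call therefore covers these 7 genes and not a basal or squamous programme as a whole. Sfn fell from 19.3 ± 0.669 to 7.35 ± 0.304 FPKM, the laminin gene Lama3 from 6.33 ± 0.361 to 2.03 ± 0.0615 and the basal keratin gene Krt14 from 2.53 ± 0.401 to 0.477 ± 0.201.

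Mesenchymal genes went both ways, with 6 of 18 higher and 8 lower (7 and 7 with total-reads scaling; camera, adjusted p = 0.593), and fry called the list lower on balance (adjusted p = 4.07e-05). Their median of -0.05 became 0.03 with total-reads scaling. Fry called most of the lists tested, so its call does not set the mesenchymal list apart. The matrix gene Sparc fell from 50.8 ± 1.25 to 26.5 ± 0.336 FPKM, while the metalloproteinase genes Mmp3 and Mmp14 rose from 50.5 ± 0.538 to 86.5 ± 0.0941 and from 31.3 ± 1.19 to 53.5 ± 0.129. Of 16 stem cell genes, 7 rose and 7 fell (camera, adjusted p = 0.956). The median of this list was 0.00 and its mean -0.07, camera pointed up and fry down, and the median was -0.01 with voom. The drug exporter genes Abcb1b and Abcg2 fell from 11.4 ± 0.370 to 4.18 ± 0.0833 and from 0.820 ± 0.0369 to 0.184 ± 0.0174 FPKM, while Cd44 rose.

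Genes of antigen presentation by MHC class I fell, with 16 of 20 lower and 2 higher (median log2 change -0.49; camera, adjusted p = 0.000176). The call was lost at an adjusted p = 0.197 with an estimated correlation. The immunoproteasome genes Psmb10 and Psmb9 fell from 17.8 ± 1.39 to 5.13 ± 0.168 and from 3.14 ± 0.175 to 0.878 ± 0.0689 FPKM, and H2-T23 from 16.7 ± 0.982 to 8.40 ± 0.152. Of 18 NF-kB targets, 15 fell and 3 rose (median -0.49; camera, adjusted p = 0.00381, and adjusted p = 0.174 with an estimated correlation). The adhesion molecule gene Vcam1 fell from 12.7 ± 0.207 to 2.20 ± 0.144 FPKM and the NF-kB subunit gene Relb from 9.83 ± 0.154 to 4.34 ± 0.135. Ptgs2, which encodes the prostaglandin synthase COX-2, rose from 45.1 ± 0.233 to 136 ± 0.209 FPKM.

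Chemokine and cytokine genes also fell for the most part, with 14 of 21 lower and 6 higher (median log2 change -0.66; camera, adjusted p = 0.0381, and adjusted p = 0.447 with an estimated correlation). Without roscovitine replicate 3 the list's camera call was lost (adjusted p = 0.0600). Ccl20 fell from 4.23 ± 0.339 to 0.258 ± 0.0482 FPKM, Cx3cl1 from 16.3 ± 0.694 to 4.05 ± 0.360 and the monocyte attractant gene Ccl2 from 10.2 ± 0.584 to 2.65 ± 0.294. Interferon-stimulated genes went both ways, with 12 of 27 higher and 5 lower (camera, adjusted p = 0.638). Their median was 0.05 and their mean -0.02, camera pointed up and fry down. Isg20 fell from 60.7 ± 3.98 to 16.5 ± 0.398 FPKM, Irf1 from 18.1 ± 0.231 to 8.80 ± 0.200 and Parp14 from 2.84 ± 0.253 to 1.40 ± 0.0936. Of 12 genes of immune ligands and checkpoints, 4 rose and 7 fell (median -0.29; camera, adjusted p = 0.354). The galectin genes Lgals9 and Lgals3 fell from 11.3 ± 0.638 to 4.52 ± 0.253 and from 184 ± 5.53 to 107 ± 2.22 FPKM, and the ectonucleotidase gene Nt5e from 20.2 ± 0.377 to 13.7 ± 0.155.

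Stress response genes showed the lowest median of the lists tested. Of 28 genes of the unfolded protein and integrated stress responses, 23 fell and 2 rose (median log2 change -0.82; camera, adjusted p = 1.55e-07, and adjusted p = 0.174 with an estimated correlation). Beside Chac1 and Trib3, the asparagine synthetase gene Asns fell from 102 ± 1.72 to 22.5 ± 0.851 FPKM. Of 28 hypoxia and glycolysis genes, 25 fell and 3 rose (median -0.64; camera, adjusted p = 2.67e-08, and adjusted p = 0.174 with an estimated correlation). Beside Adm, Ankrd37 fell from 7.45 ± 0.250 to 1.17 ± 0.231 FPKM and the carbonic anhydrase gene Car9 from 57.4 ± 0.330 to 16.7 ± 0.876. Of 20 targets of the oxidative stress factor NRF2, 12 fell and 2 rose (13 and 2 adjusted over the list alone, 12 and 5 with total-reads scaling; median -0.29; camera, adjusted p = 0.0118, and adjusted p = 0.174 with an estimated correlation). The cystine transporter gene Slc7a11 fell from 1.43 ± 0.0978 to 0.225 ± 0.0241 FPKM, Gstm1 from 1.02 ± 0.157 to 0.315 ± 0.0451 and Osgin1 from 6.07 ± 0.160 to 3.62 ± 0.326. Of 5 targets of the aryl hydrocarbon receptor, 4 fell and 1 rose (median -0.35; camera, adjusted p = 0.211). Among them Aldh3a1 fell from 1.46 ± 0.148 to 0.464 ± 0.0868 FPKM, Nqo1 from 4.32 ± 0.524 to 2.56 ± 0.418 and Cyp1b1 from 0.920 ± 0.145 to 0.505 ± 0.0177.

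Lysosome and autophagy genes rose, with 19 of 27 higher and 6 lower (median log2 change 0.35; camera, adjusted p = 0.00652, and adjusted p = 0.358 with an estimated correlation). The sialidase gene Neu1 rose from 5.15 ± 0.317 to 13.3 ± 0.317 FPKM and Mcoln1, a lysosomal cation channel gene, from 5.30 ± 0.178 to 9.80 ± 0.194, while Atg9b fell from 23.9 ± 0.716 to 11.4 ± 0.203. Targets of PPARγ and lipid droplet genes went both ways, with 5 of 14 higher and 5 lower (camera, adjusted p = 0.945). Their median of -0.01 became 0.08 with total-reads and 0.01 with upper-quartile scaling, and fry pointed up where camera pointed down. Plin2, which encodes a lipid droplet coat protein, rose from 80.6 ± 0.595 to 166 ± 3.06 FPKM, while Fabp5 fell from 24.7 ± 0.734 to 11.8 ± 0.623 and the lipase gene Pnpla2 from 28.4 ± 0.727 to 19.9 ± 0.583. Of 23 cholesterol synthesis genes, 10 rose and 7 fell (13 and 5 with total-reads scaling; median 0.04; camera, adjusted p = 0.538). Hsd17b7 rose from 4.10 ± 0.326 to 16.6 ± 0.299 FPKM, Sc5d from 15.7 ± 0.278 to 28.0 ± 0.274 and Dhcr24 from 37.6 ± 0.390 to 62.1 ± 0.780.

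Immediate early genes, transcribed soon after a stimulus, rose in 17 of 26 cases and fell in 6 (median log2 change 0.32; camera, adjusted p = 0.0118, and adjusted p = 0.374 with an estimated correlation). The phosphatase gene Dusp5 rose from 27.8 ± 1.68 to 58.6 ± 2.57 FPKM, Ier5 from 19.9 ± 1.13 to 34.5 ± 0.276 and Fosb from 1.53 ± 0.201 to 3.04 ± 0.245. In the BCL2 family, 7 of 13 rose and 3 fell (median 0.15 and mean 0.00; camera, adjusted p = 0.538). Bcl2l11, which encodes the pro-apoptotic protein BIM, rose from 11.6 ± 0.659 to 18.01 ± 0.153 FPKM, while Bbc3 fell and the pro-survival gene Bcl2l2 fell from 4.97 ± 0.488 to 2.71 ± 0.292.

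Target lists of 3 developmental pathways did not stand apart in camera. Fry, which called most lists, called WNT lower (adjusted p = 0.0464), NOTCH higher (adjusted p = 0.00655) and YAP and TEAD lower (adjusted p = 4.2e-05). Of 10 WNT targets, 3 rose and 5 fell (median -0.16; camera, adjusted p = 0.593), against 3 and 2 with total-reads scaling. Fzd1 fell from 1.31 ± 0.135 to 0.722 ± 0.0893 FPKM and Wnt10a from 1.92 ± 0.251 to 1.17 ± 0.0880, while Znrf3 rose from 2.85 ± 0.0556 to 3.75 ± 0.176. Of 9 NOTCH targets and ligands, 4 rose and 1 fell (3 and 1 adjusted over the list alone, 6 and 1 with total-reads scaling; median 0.15; camera, adjusted p = 0.427). The ligand genes Dll4 and Jag2 rose from 1.73 ± 0.210 to 3.04 ± 0.145 and from 3.27 ± 0.208 to 3.90 ± 0.0929 FPKM, and Dtx4 fell from 5.75 ± 0.456 to 4.57 ± 0.138. Of 16 YAP and TEAD targets, 5 rose and 9 fell (7 and 8 with total-reads scaling; median -0.17; camera, adjusted p = 0.335). The receptor kinase gene Axl fell from 296 ± 1.79 to 144 ± 2.38 FPKM, Gadd45b from 66.1 ± 3.74 to 21.6 ± 1.07 and the tissue factor gene F3 from 6.34 ± 0.185 to 3.05 ± 0.211.

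Cytosolic ribosomal protein genes fell as a group, with 38 of 41 lower and 0 higher (median log2 change -0.55; camera, adjusted p = 6.85e-13). The call was lost at an adjusted p = 0.185 with an estimated correlation. Rps3 fell from 421 ± 5.13 to 226 ± 1.94 FPKM, Rps8 from 800 ± 36.4 to 444 ± 6.44 and Rps9 from 618 ± 14.2 to 352 ± 5.26. Such genes share sequence with many processed pseudogenes, whose share of reads was 2.57 ± 0.04% in vehicle and 2.07 ± 0.05% in roscovitine. Genes encoded by the mitochondrial genome rose, with 8 of 13 higher and 0 lower (12 and 0 with total-reads scaling; median 0.37; camera, adjusted p = 0.00866, and adjusted p = 0.174 with an estimated correlation). The complex I gene mt-Nd1 rose from 2239 ± 34.2 to 3213 ± 65.6 FPKM and the cytochrome oxidase gene mt-Co2 from 98.2 ± 9.65 to 152 ± 21.1. The related mt-Co3 rose from 21.3 ± 4.18 to 35.7 ± 11.4 FPKM (limma, adjusted p = 0.0324). Its limma call was lost without vehicle replicate 2, vehicle replicate 3 or roscovitine replicate 1 (adjusted p = 0.0933, 0.0928 and 0.0538) and with no level filter (adjusted p = 0.0772). Mitochondrial genes held 1.76 ± 0.02% of reads in vehicle and 2.43 ± 0.02% in roscovitine (SD, n = 3).

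RNA processing and splicing genes went both ways, with 7 of 29 higher and 15 lower (8 and 15 adjusted over the list alone; median log2 change -0.08; camera, adjusted p = 0.0576). Without roscovitine replicate 2 the list passed camera (adjusted p = 0.0478), and with total-reads scaling 11 rose and 13 fell and its median became 0.01. The splicing factor genes Hnrnpa1 and Hnrnph1 fell from 430 ± 9.33 to 98.6 ± 2.62 and from 101 ± 0.0815 to 31.1 ± 0.531 FPKM, and Tra2a from 22.3 ± 0.867 to 13.1 ± 0.400. Among 12 housekeeping genes, often used as references, 2 rose, 7 fell and 3 did not pass (3 rose and 5 fell with total-reads scaling; median -0.26). Beside Gapdh, Pgk1 fell from 1142 ± 15.4 to 435 ± 6.95 FPKM and Hprt from 64.8 ± 2.55 to 35.6 ± 0.648.

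**Figure D3:**
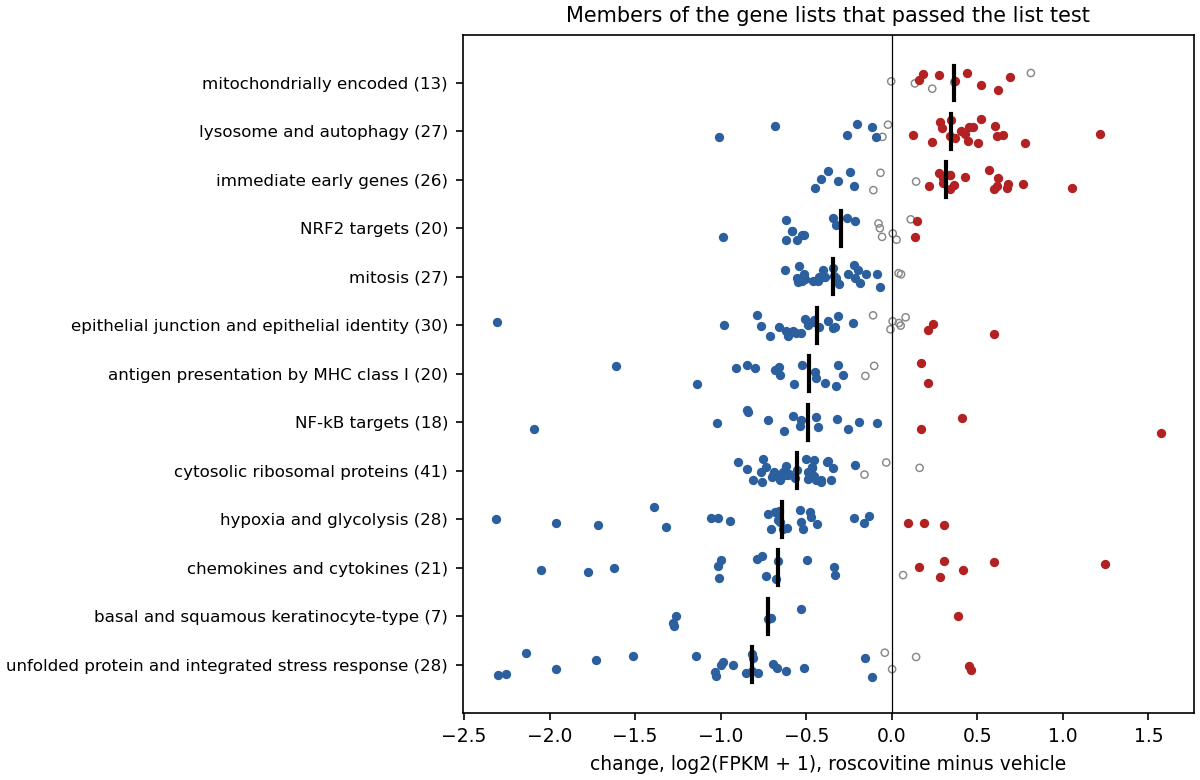
Change in log2(FPKM + 1), roscovitine minus vehicle (horizontal axis), of each tested member of the 13 lists that passed camera, with the number of members in brackets. Red and blue points are members that rose and fell, open points did not pass, and the black bar is the list's median, from 0.37 for mitochondrially encoded genes to -0.82 for stress response genes.

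Markers of other cell types were low or few. Of 17 retina markers 1 had a mean of at least 1 FPKM, Rom1, at 1.80 ± 0.504 in vehicle and 0.880 ± 0.0546 in roscovitine. Of 16 myeloid markers 3 reached that level, led by the lysosomal protein gene Cd68 at 21.4 ± 1.24 and 19.1 ± 0.832 FPKM. The lymphocyte list had 1 of 14, Cd79a, at 0.465 ± 0.182 and 1.63 ± 0.161. The fibroblast list had 1 of 12, Pdgfra, at 4.25 ± 0.123 and 3.64 ± 0.326, and the endothelial list 1 of 10, Eng, at 10.6 ± 0.464 and 13.4 ± 0.751. In these lists 3 retina, 3 myeloid, 3 lymphocyte, 1 fibroblast and 3 endothelial genes passed the level filter, of which 1, 0, 1, 0 and 2 rose and 1, 2, 1, 1 and 0 fell. The mesenchymal list also holds 2 of the fibroblast genes.

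Counts adjusted over the list alone were equal to those over all genes in the lists above where no count of that kind is given, except that 2 retina markers rose over the list alone. The medians of the 13 lists that passed camera kept their sign with total-reads scaling, upper-quartile scaling and voom, and 0 of the 13 passed with the correlation estimated from the data.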

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

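With limma, the count of changed genes, of those that rose and of those that fell stayed within 1.5 times of 9510, 4780 and 4730 in each alternative run. Counts of larger changes depended on the pseudocount by its construction. Log2 changes of at least 1 upward were reached by 688 genes with voom on the implied reads, by 639 with a pseudocount of 0.1 and by 415 with 0.5, and downward by 877 with voom and 777 with 0.1 (pseudocounts chosen after seeing the data). Against 13 list calls, camera with an estimated correlation made 0 and fry, which tests another question, 28. Leaving out 1 library at a time gave 8894 to 9026 changed genes, 4449 to 4535 higher, 4407 to 4491 lower, 217 to 230 and 327 to 347 with a log2 change of at least 1 up and down, and 12 to 14 list calls. With a block for replicate number, 9164 genes changed and the chemokine list lost its call (adjusted p = 0.0503). Deviations of same-numbered libraries correlated at -0.0184, -0.0489 and 0.0200, and not every library correlated best with its own number, so the numbers were not treated as pairs. Over all alternatives and named genes, 1669 results kept their side of the threshold, 10 lost the call, all of Gapdh or mt-Co3, and 1 gained it, Esrp2. Among list results 389 kept their side, 15 lost and 16 gained the call; the causes were not tested. No named gene or list that had passed at first changed sign, but the stem cell list, which had not, turned from up to down and passed with fry (adjusted p = 8.66e-05). Median-of-ratios scaling moved nothing, because the deposited values already carry it, and says nothing about stability. The planned count-based fits were not run, since the unit is FPKM, and limma fits of the same choices stand in their place. Depth limits genes near 0.0442 to 0.0569 FPKM per read at 1 kb, such as Pparg.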

Other observations

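A pair of adjacent genes on chromosome 17 and the mitochondrial ribosomal RNA genes rose after roscovitine. These genes were singled out after their values were seen. Gm26917, annotated as a long intergenic noncoding RNA (39843013 to 39846341), rose from 138 ± 4.99 to 1281 ± 9.77 FPKM, a log2 change of 3.20 ± 0.03 (limma, adjusted p = 8.95e-08). It lies beside CT010467.1, which is annotated as ribosomal RNA (39846353 to 39848827) and rose from 2.68 ± 0.193 to 14.5 ± 0.814 FPKM. The mitochondrial ribosomal RNA genes mt-Rnr1 and mt-Rnr2 rose from 115 ± 0.560 to 212 ± 7.79 and from 119 ± 2.21 to 162 ± 2.85 FPKM. The other ribosomal RNA genes with a mean of at least 5 FPKM did not pass the test, Gm23964 on chromosome 17 at 9.58 ± 2.06 and 11.1 ± 1.37 FPKM (limma, adjusted p = 0.276) and Gm26280 at 6.48 ± 3.69 and 5.63 ± 1.71 (limma, adjusted p = 0.816). Gm26917 held 0.0448 ± 0.0014% of reads in vehicle and 0.443 ± 0.004% in roscovitine, all other long intergenic noncoding RNA 0.393 ± 0.009% and 0.353 ± 0.014%, and genes annotated as ribosomal RNA 0.0302 ± 0.0004% and 0.0517 ± 0.0017%. The share of ribosomal RNA goes by annotation and leaves out Gm26917. Whether the reads at Gm26917 derive from ribosomal RNA was not tested, so its rise need not be that of a separate noncoding gene. The 100 most abundant genes held 20.4 ± 0.143% of reads in vehicle and 17.0 ± 0.0569% in roscovitine, led by the translation factor gene Eef1a1 in every vehicle library and by mt-Co1 in every roscovitine library.

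Chosen only after the result was seen were the total-reads test of ribosomal protein genes, the immediate early test, the tests of genomic span and the test by the direction of the neighbour, which was added once the shares by position were known. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many changed genes with limma as the real one, the real split itself at 9510, and the highest of the others gave 0. So few splits cannot give a share under 0.1.

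The 41 cytosolic ribosomal protein genes had a median log2 change of -0.55. Random lists matched on transcript length and mean FPKM had a median of -0.28 with a 2.5% limit of -0.45, so the list lay below them. The pool for matching left out only the 41 listed genes and could hold other ribosomal protein genes. The -0.28 therefore does not show that short, abundant genes fell in general. Across 10 groups of protein-coding genes of rising transcript length, the median log2 change was -0.15 in the shortest group, of 1106 genes. In the other groups it was -0.02 to 0.05, so the shortest transcripts were lower as a class, by less than the list. The shortest group can also hold ribosomal protein genes. Scaling to total reads alone moved the median of all genes to 0.07 and left the list at -0.46 (95% interval -0.54 to -0.38). The fall therefore does not rest on the choice between these scalings, but that choice moved all genes too little to remove it. All scalings used are relative, so levels per cell were not tested. Reads lost to pseudogene copies would raise those copies, and the 106 tested ribosomal protein pseudogenes had a median of -0.39 (-0.50 to -0.34), with 1 higher and 61 lower. An effect of roscovitine on these transcripts stays open as a hypothesis, as do differences in RNA integrity or selection that the labels do not describe.

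The 56 stress response and hypoxia genes together had a median log2 change of -0.69, below the random lists matched on length and FPKM, at -0.04 with a 2.5% limit of -0.17. A general fall of short-lived transcripts, which a CDK inhibitor that also meets transcription kinases could give, would lower immediate early genes too, unless they were newly induced. The median of the immediate early list was 0.32 (0.04 to 0.47), so these genes did not fall as a set. Because a stimulus can induce them, their level at 24 h cannot decide whether other short-lived transcripts fell, and that explanation stays open. A fall of stress signalling in treated cells stays open and was not tested, as do differences between wells in density, medium or oxygen, which the labels do not describe.

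Protein-coding genes under 1 FPKM in vehicle rose more often when they lay beyond the 3' end of an expressed gene. Expressed means at least 5 FPKM in vehicle, and rises were taken from the fit with no level filter. Genes without a read in any library could not be called but stayed in the totals, and their share by position was not examined. Within 10 kb beyond a 3' end on the same strand 126 of 392 rose (32.1%) and 5.36% fell. Beside the 3' end of a convergent gene 112 of 581 rose (19.3%) and 3.96% fell. Beside the 5' end of a divergent gene 34 of 248 rose (13.7%) and 5.65% fell. Before the 5' end of a same-strand gene 26 of 372 rose (6.99%) and 5.91% fell. With the nearest expressed gene at 10 to 50 kb 180 of 2290 rose (7.86%) and 5.72% fell. With none within 50 kb 144 of 7035 rose (2.05%) and 2.81% fell. Of genes that overlap an expressed one 17.5% rose, and of those with one on both sides 28.2%. The odds ratio of same-strand 3' ends against divergent 5' ends was 2.98 (exact 95% interval 1.93 to 4.68, Fisher's exact p = 7.89e-08), as transcription running past gene ends would give, though the notes do not state the use of strand. Genes beside divergent ones rose more often than genes far from expressed ones (odds ratio 7.60, 4.94 to 11.4). A rise of every nearby gene would give this, but so could undetected genes, if more frequent far from expressed ones. The 6.99% (4.81 to 10.0) before 5' ends against 32.1% (27.7 to 36.9), shares already seen, argues against a like rise at every position. Falls were also more frequent near expressed genes. Beyond neighbours that rose 61 of 163 genes rose (37.4%, 30.4 to 45.1), beyond those that did not pass 25 of 83 (30.1%) and beyond those that fell 40 of 146 (27.4%, 20.8 to 35.1), which argues against a rise of the neighbour as the whole cause but leaves a part open, so read-through is a candidate explanation, as for Colec11 beyond Rps7, which fell from 348 to 214 FPKM, though gene-level values cannot separate it from a start at the gene's own promoter.

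Inhibitors of transcription elongation might lower long genes most. Across 11041 protein-coding genes, Spearman's rho of the log2 change with genomic span was 0.0168 (permutation p = 0.0790, 2-sided; Pearson's r 0.0259), where genes are not independent replicates. Over 10 groups of rising span, the median log2 change ran from -0.11 in the shortest to a peak of 0.05 at a median span of 14398 bp and to -0.02 in the longest. The decline after the peak was not steady, with -0.01 at a median span of 52517 bp and 0.03 at 82976 bp. From the peak group up rho was -0.0535 (95% interval -0.0757 to -0.0317), a part picked for its peak, so a weak fall with span beyond short genes stays open.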
